A study of Homo sapiens with 6 samples.

How the data were processed

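RNA abundance was measured by RNA sequencing in 6 libraries of U937 cells, an established human myeloid cell line first grown from a histiocytic lymphoma and described in the labels as acute myeloid leukemia. Cells were held in RPMI-1640 without serum and received 1 µM of a compound named only B2, or its DMSO vehicle, for 36 h, with 3 libraries per group. Total RNA was isolated with TRIzol, per the labels' protocols. The labels call the libraries replicates without saying that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

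The authors deposited 1 table of estimated counts (expected counts) for 60612 Ensembl gene identifiers, not normalized. Alignment used HISAT2 2.0.4, per the submitters' processing notes. The counting tool, genome build, annotation and strand setting are not given in the sources used here. The deposited values were whole numbers already, so rounding changed nothing. Among low values, 4 occurred 6465 times over the 6 libraries against 3144 times for 3 and 2022 times for 5, a step that a plain tally of reads would not give. Small counts are therefore less exact than their size implies, and counts divided by 4 were run as an alternative. Of the identifiers, 60401 matched a symbol in a gene name table and 187 more were named from GENCODE release 29. Positions (GRCh38, GENCODE 29) were found for 58394 identifiers and come from that annotation, not from the authors' files. Genes whose exons overlap another gene on the same strand can share or exchange reads, and their values are uncertain.

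Library totals ran from 61150740 to 78431054 counts. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 17224. Libraries were scaled with TMM factors between 0.86 and 1.07. The comparison of B2 with DMSO used edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest, treatment as the only term), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Every adjusted p for a single gene is from this test unless another tool is named. Fold changes are B2 over DMSO on the log2 scale, standard errors (SE) were taken from the fitted coefficient and its F statistic, and CPM values are counts divided by the TMM-scaled library total in the usual way. The 44 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, again with a camera-estimated correlation, and with fry, each adjusted over the lists. The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

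The rule for named genes took S100A9 and S100A8 first, then genes past the threshold by fold and by p (there were none), then up to 4 members with the smallest p of each called list and up to 2 of each other list, then ACTB, GAPDH, B2M and PPIA. It gave 93 genes, of which the text prints a part, picked after the values were seen, and every one was run under the alternatives. Genes named outside the rule are marked as chosen after their values were seen.

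Both groups carry replicate numbers 1 to 3. Deviations of same-numbered libraries from their group means, across genes, correlated at 0.21 for number 1, 0.40 for number 2 and 0.50 for number 3, and 6 of 6 libraries correlated best with their own number. By a rule not fixed before the data were seen (each above 0.1) the numbers were taken to pair the libraries. Passing it is therefore no test of pairing. The pairing comes from the data, since the labels do not say what a number marks. Deviations within a group sum to 0, so the strong match of number 3 constrains the other values, which are not independent support. Without that centering, log2 CPM of B2 replicate 1 correlated better with DMSO replicate 2 (Pearson r 0.964 across genes) than with DMSO replicate 1 (0.959). The pairing of number 1 is therefore weak. A fit with the replicate number as a block was run beside the main one.

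The tests were checked on simulated counts with 200 changed genes among 17224. With the spread of the fit without block, that fit recovered 1 of 50 genes changed 1.5-fold, 0 of 50 changed 2-fold, 9 of 50 changed 4-fold and 34 of 50 changed 8-fold, and it called 7 unchanged genes. With replicate-number differences like those of the real libraries, the fit without block recovered 0, 0, 0 and 17 of 50 at these folds. The blocked fit recovered 0, 7, 38 and 45 of 50, with 10 unchanged genes called. Simulated counts were drawn independently around the fitted means, without trends that many genes of a library share. Recovery by the blocked fit may therefore be overstated. Alternatives were RLE factors, upper-quartile factors, library totals, 2 other filters on low counts, DESeq2 1.42.0 (on all genes, with its own filtering), limma-voom, the block, removal of mitochondrially encoded genes, an adjusted p of 0.01, a tested fold of 1.2 and each library left out. Added after the data were seen were DESeq2 on the filtered genes, limma-voom without the filter, both libraries of number 3 left out (with and without block), counts divided by 4, and removal of each library's trend with transcript length and GC content (with and without block).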

Results

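The data are gene-level RNA sequencing counts from U937 cells kept without serum and exposed for 36 h to 1 µM B2 or to DMSO. The total count was 71825659, 68139863 and 61150740 in B2 replicates 1, 2 and 3, and 64807118, 72404425 and 78431054 in the DMSO replicates of the same numbers. Mitochondrially encoded genes held between 6.44% and 10.3% of the counts. The series title names S100A9, a calcium-binding alarmin of myeloid cells, as the target, and the single comparison asks how B2 alters gene expression.

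S100A9 (chromosome 1, 153357854 to 153361027) did not differ detectably between the groups. It stood at 239 ± 374 CPM with B2 and 219 ± 333 CPM with DMSO (mean ± SD, n = 3 each), a log2 fold change of 0.12 with an SE of 1.54 and a 95% interval from -3.41 to 3.65 (edgeR adjusted p = 1.0). Its partner S100A8, with which it forms the calprotectin heterodimer, stood at 17.4 ± 28.4 CPM with B2 and 11.999 ± 19.1 CPM with DMSO (log2 fold change 0.53, SE 1.72; -3.60 without B2 replicate 3 and 4.16 without DMSO replicate 3). The spread came from replicate number 3: S100A9 read 670 CPM in B2 replicate 3 and 603 CPM in DMSO replicate 3, against 17.6 to 37.1 CPM in the other 4 libraries. S100A8 read 50.2 and 34.1 CPM in the libraries numbered 3 and at most 1.05 CPM elsewhere. With the replicate block the S100A9 estimate was -0.06 with an SE of 0.25. Without B2 replicate 3 it was -3.27, and without DMSO replicate 3 it was 3.13. The S100 family list was not called in the main test (17 tested, 8 positive, 9 negative, median -0.02, camera adjusted p = 0.620). It was called with all libraries under the stricter filter on low counts and with counts divided by 4. Its members S100A14 (log2 fold change 2.15, SE 1.25) and S100A16 (1.40, SE 0.62) did not pass the test. S100A14 read 1.79, 1.10 and 1.82 CPM in B2 replicates 1 to 3 and 0, 0.05 and 0.99 CPM in the DMSO replicates. S100A16 read 2.17, 1.33 and 2.20 CPM with B2 and 0.27, 0.52 and 1.37 CPM with DMSO. Both were thus lowest in DMSO replicates 1 and 2, as was the keratin KRT8 described below.

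**Figure D1:**
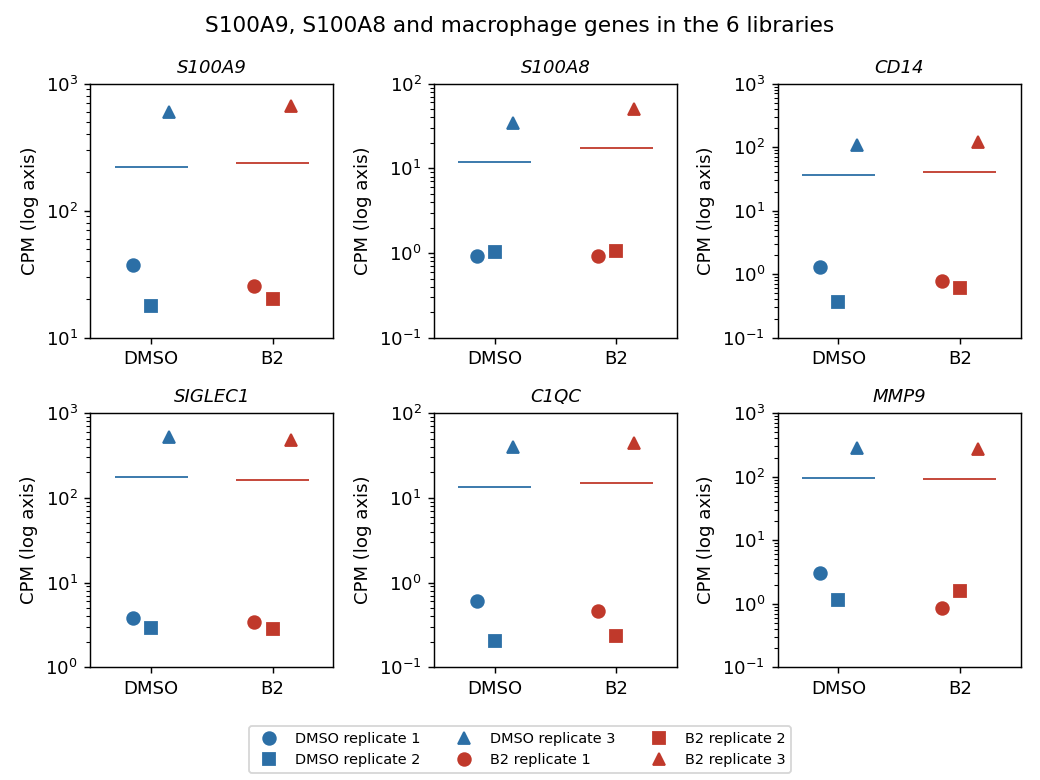
CPM on a log axis for S100A9, S100A8 and 4 macrophage genes chosen after their values were seen, with 1 point per library, marker shape for the replicate number and a line at each group mean. In each panel both libraries numbered 3 lie above the other 4, and S100A9 reads 670 and 603 CPM there.

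No gene passed the test between B2 and DMSO. Of 17224 genes, 0 had an edgeR adjusted p below 0.05, with a smallest adjusted p of 0.674, and 0 did with the replicate block, with a smallest of 0.127. The smallest edgeR adjusted p was 0.0507, just above the threshold, with the block and the length and GC trend removed. At an unadjusted p below 0.05 there were 85 genes (57 higher and 28 lower with B2), or 228 with the block, which is 0.493% and 1.32% of the genes tested. In simulated counts with replicate-number differences like the real ones, 0.576% of the unchanged genes lay below that p without the block and 4.34% with it. Limma-voom on the same genes called 0. DESeq2, run without that filter on 28655 genes, called 3, all without a symbol: ENSG00000285839 higher with B2, and ENSG00000217576 and ENSG00000273433 lower. ENSG00000285839 had 4157, 7 and 1753 counts in B2 replicates 1 to 3 and at most 6 with DMSO, and ENSG00000273433 had 0 counts in each B2 library and 54 to 113 with DMSO. The exons of each of the 3 overlap another gene, so their values are uncertain. ENSG00000273433 was the 1 gene of the 3 in the edgeR test, and the 1 gene called by DESeq2 on the filtered genes and by limma-voom without the filter, where edgeR without the filter called 0 of 28792. These 3 were named after their values were seen, and ENSG00000285839 was also the 1 gene that edgeR called without B2 replicate 2.

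The median SE of a log2 fold change was 0.41, and 35.9% of the genes had a 95% interval lying wholly within a 2-fold change either way. The reference genes had log2 fold changes of -0.26 for ACTB (SE 0.29), -0.20 for GAPDH (SE 0.35) and -0.06 for B2M (SE 0.63), while PPIA lay at 0.00 and changed sign under another scaling. Without DMSO replicate 1 ACTB was at -0.04 and GAPDH at 0.23, and B2M ran from -0.85 without B2 replicate 3 to 0.71 without DMSO replicate 3. The median over all genes was -0.08. Of all genes, 614 (3.56%) had groups that did not overlap, where chance gives 10% if all libraries are exchangeable, which the resemblance of same-numbered libraries makes doubtful. The 3 pairs had 1 direction in 2741 genes (15.9%), where chance gives 25% if the pairs are independent. That is doubtful, since the trend with GC content differed in opposite directions in pairs 1 and 2. It was 0.20 with B2 and 0.48 with DMSO in number 1, and -0.27 and -0.55 in number 2 (Spearman across genes). The B2 minus DMSO difference of pair 1 correlated with that of pair 2 at -0.06, pair 1 with pair 3 at 0.06 and pair 2 with pair 3 at -0.02 (Pearson r across genes, which are not independent replicates), and by rank at -0.25, 0.08 and -0.11 (Spearman).

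Genes of inflammatory signalling did not pass the test, and with all libraries their list medians lay close to the -0.08 of all genes. None of the 31 tested S100A9 receptor and Toll-like receptor genes was called (8 positive, 23 negative, median -0.16, camera adjusted p = 0.832). TLR5, the flagellin receptor, stood at 0.527 ± 0.0592 CPM with B2 and 0.990 ± 0.606 CPM with DMSO, and the kinase IRAK4 at 9.37 ± 3.05 and 13.2 ± 8.97 CPM (log2 fold change -0.50; 0.17 without DMSO replicate 2 and -0.80 without DMSO replicate 1). Among 28 NF-kB targets 0 were called (median -0.11), with BIRC3, an inhibitor of apoptosis, at -0.97 (SE 0.97; 0.64 without DMSO replicate 3 and -2.07 without B2 replicate 3). Among 33 interferon-stimulated genes 0 were called (median -0.08), with IFIT2, a gene whose exons overlap another gene, at -0.77 (SE 0.74; -0.05 without DMSO replicate 3 and -1.65 without B2 replicate 3). Of 34 monocyte and macrophage markers 15 were positive and 19 negative (median -0.05), and the lysosomal protease LGMN read 0.891 ± 0.131 CPM with B2 and 0.525 ± 0.103 CPM with DMSO. These list calls depended on single libraries: without B2 replicate 3 camera called the receptor list (median -0.46), NF-kB targets (-0.67), interferon-stimulated genes (-1.31) and macrophage markers (-0.74) lower with B2, and without DMSO replicate 3 it called the last 3 higher (0.61, 0.98 and 0.57), as it did interferon-stimulated genes (0.25) and macrophage markers (0.18) without B2 replicate 2.

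Cell cycle and survival genes gave the same outcome. No member of the 45 DNA replication genes, 40 G2/M genes, 27 p53 targets or 34 apoptosis regulators was called. RFC3, a clamp loader subunit, had a log2 fold change of -0.53 (SE 0.32), the spindle checkpoint gene MAD2L1 -0.48 (SE 0.29), and PRC1, a midzone protein whose exons overlap another gene, 0.52 (SE 0.39). CCNG1, a p53 target, read 65.2 ± 4.20 CPM with B2 and 91.4 ± 21.7 CPM with DMSO (log2 fold change -0.49, SE 0.26), and PMAIP1, which encodes the BH3-only protein NOXA, 7.02 ± 0.716 and 10.3 ± 3.78 CPM. RFC3 was at -0.30 and PRC1 at 0.97 without DMSO replicate 2, PRC1 at 0.31 without DMSO replicate 3, and CCNG1 at -0.28 without DMSO replicate 1. The p53 list had a median of -0.18 and a camera adjusted p of 0.435, but was called without B2 replicate 3 (median -0.42), where the DNA replication list was called higher (0.14). Without DMSO replicate 3 the DNA replication list was called lower (-0.18), and G2/M was called lower there and without B2 replicate 2 (-0.22 and -0.21). Among 30 stem cell and leukemia regulators 15 were positive and 15 negative.

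The ribosomal protein, cholesterol synthesis and MYC target lists had more negative than positive members, and none was called with all libraries. A negative median was found in 41 of the 44 lists with TMM factors, where the median of all genes was itself negative (-0.08). The 74 ribosomal protein genes counted 67 negative members (median -0.17, camera adjusted p = 0.345), with RPL7 at 489 ± 117 CPM with B2 and 695 ± 271 CPM with DMSO. Of 25 cholesterol synthesis genes 21 were negative (median -0.20, adjusted p = 0.345). IDI1, the isopentenyl diphosphate isomerase, stood at 89.1 ± 9.77 and 125 ± 25.7 CPM and SC5D, a late sterol desaturase, at 18.4 ± 2.28 and 27.7 ± 7.18 CPM. Of 40 MYC target and ribosome biogenesis genes 30 were negative (median -0.19, adjusted p = 0.464), NPM1 among them at -0.53 (SE 0.33; -0.33 without DMSO replicate 2). With library totals as the only scaling, where the median of all genes was 0.0006, 51 ribosomal protein genes were negative (median -0.04) and 19 cholesterol synthesis genes (median -0.08). Camera called the ribosomal protein list lower with B2 without B2 replicate 1 (median -0.27), DMSO replicate 2 (-0.35), DMSO replicate 3 (-0.37) or both libraries numbered 3 (-0.32, and -0.24 with the block), and higher without DMSO replicate 1 (0.26, adjusted p = 1.1e-11). It called cholesterol synthesis and MYC targets lower without B2 replicate 2 (-0.24 each) and without DMSO replicate 3 (-0.36 and -0.31). The ribosomal protein median was -0.58 in pair 1, 0.11 in pair 2 and 0.23 in pair 3.

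**Figure D2:**
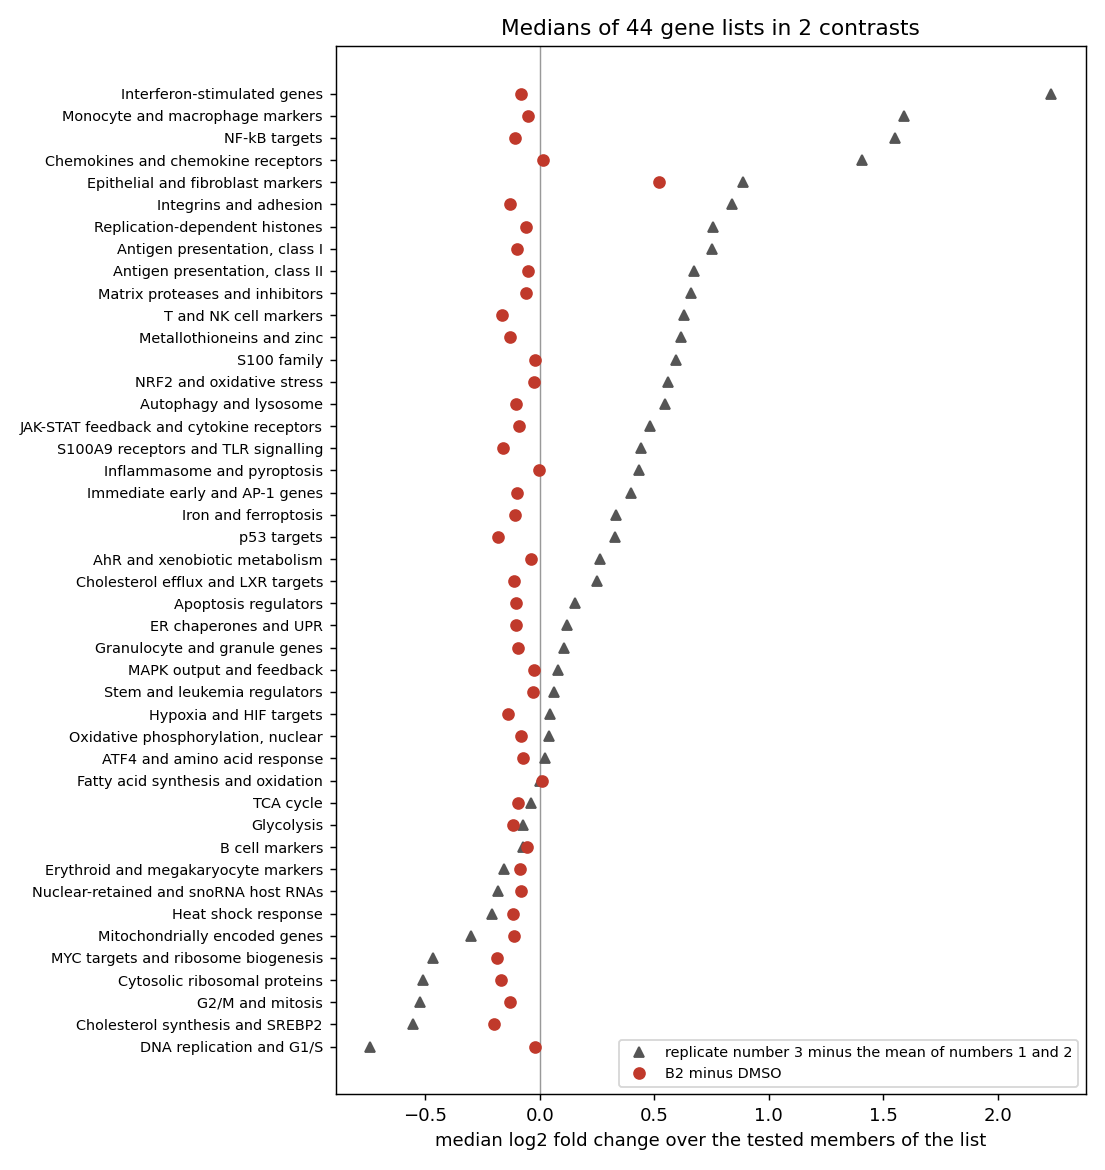
Median log2 fold change over the tested members of each of the 44 lists, as circles for B2 minus DMSO and triangles for replicate number 3 minus the mean of numbers 1 and 2, a contrast chosen after the data were seen. The circles of 43 lists lie within 0.25 of 0 and the epithelial and fibroblast list lies at 0.52, whereas the interferon-stimulated triangle lies at 2.23.

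Epithelial and fibroblast markers were the 1 list of 44 that passed camera at the preset correlation, and it was higher with B2 (camera adjusted p = 1.9e-05; 9 of 13 tested members positive; median 0.52). The call was lost with an estimated correlation (adjusted p = 0.996) and with fry (adjusted p = 0.972), and without DMSO replicate 2 (adjusted p = 0.0941), and the median was 0.09 without B2 replicate 3. Camera also called this list for groupings that mix the treatments. Its camera adjusted p was 6.0e-04 for B2 replicates 1 and 3 with DMSO replicate 3 against the rest. For B2 replicate 1 with DMSO replicates 1 and 2 against the rest it was 2.4e-04. Leaving out 1 library gave 2, 9 and 16 called lists for B2 replicates 1, 2 and 3, and 3, 2 and 18 for DMSO replicates 1, 2 and 3. The epithelial list was fixed as a check for cell types foreign to a myeloid culture. The keratin KRT8 read 10.9 ± 0.453 CPM with B2 and 3.96 ± 4.61 CPM with DMSO, KRT18 5.99 ± 1.09 and 2.62 ± 3.02 CPM, KRT19 9.18 ± 0.837 and 3.54 ± 3.52 CPM, and the cadherin CDH1 0.566 ± 0.284 and 0.255 ± 0.0920 CPM. The 4 fibroblast and mesenchymal members, named after their values were seen, had log2 fold changes of -0.25 for FBN1, -0.19 for ACTA2, -0.18 for PDGFRB and 0.07 for COL1A1, against a median of 1.14 for the 9 epithelial members. No member passed over all genes or adjusted over the list alone, while 2 members passed over the list alone with the replicate block. DMSO replicate 3 did not share the low level, with KRT8 at 9.22 CPM against 0.663 and 1.98 CPM in DMSO replicates 1 and 2. The summed CPM of the list was 47.3, 49.0 and 62.0 in the B2 libraries and 19.2, 29.6 and 48.5 in the DMSO libraries (two-sided exact permutation p = 0.2, where the smallest possible is 0.1). It was higher with B2 in 3 of 3 pairs (exact sign-flip p = 0.25, the smallest that 3 pairs can give).

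**Figure D3:**
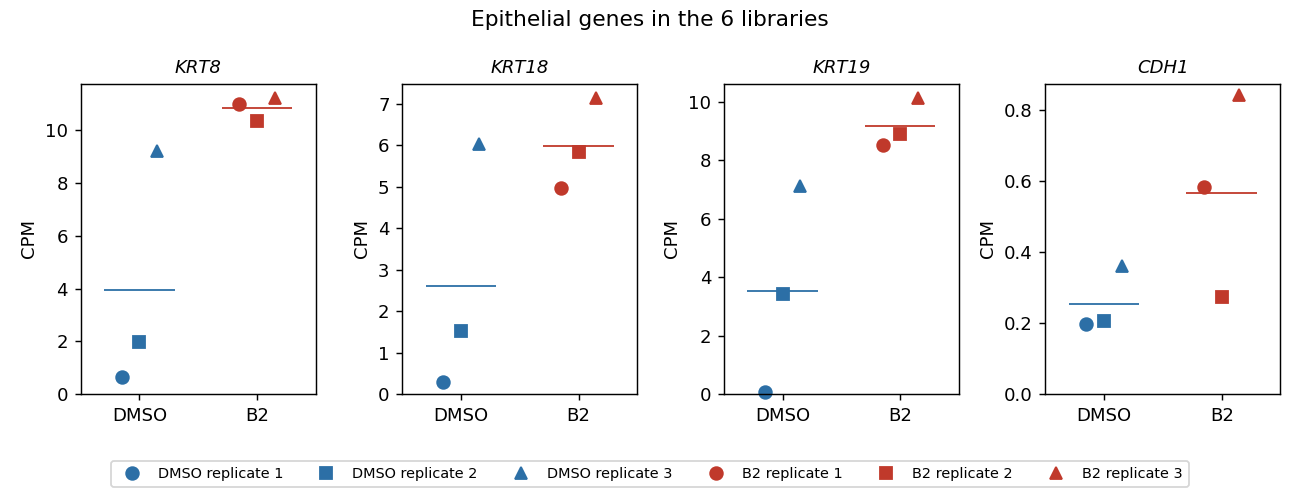
CPM of the keratins KRT8, KRT18 and KRT19 and of CDH1, with 1 point per library, marker shape for the replicate number and a line at each group mean. KRT8 lies at 0.663 and 1.98 CPM in DMSO replicates 1 and 2 and at 9.22 CPM in DMSO replicate 3, near the 10.9 CPM mean of the B2 libraries.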

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

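Alternatives with number 3 left out, counts divided by 4, the length and GC trend removed, DESeq2 on the filtered genes or limma-voom without the filter were chosen after the data were seen. An adjusted p of 0.01 and a tested fold of 1.2 are stricter cuts on the main fit, so their count of 0 was fixed in advance. With these included, the count of changed genes was 0 under 19 of the 24 other settings, and the replicate block gave 0 as well and changed no list call. The exceptions were DESeq2 without the filter on low counts, with 3 genes (1 higher, 2 lower, 3 beyond 2-fold), DESeq2 on the filtered genes and limma-voom without the filter, with 1 each (lower, beyond 2-fold), both libraries of number 3 left out with the replicate block, with 48 (31 higher, 17 lower, 48 beyond 2-fold), and the fits without 1 library, which gave 0 to 1 changed, 0 to 1 higher and 0 to 1 beyond 2-fold. The 48 rest on 2 pairs and 1 residual degree of freedom. The exons of 27 overlap another gene, 7 others are in the epithelial lists and higher with B2, and 29 had 0 counts in at least 1 of the 4 libraries. The remaining 14 were in neither set. Among these, named after their values were seen, the keratin KRT4, ERBB2 and GRB7 were higher with B2, and HLA-J and BEST1 were lower. Unadjusted counts ran from 36 (stricter filter) to 987 (without DMSO replicate 2) against 85. S100A9 ranged from -3.27 without B2 replicate 3 to 3.13 without DMSO replicate 3, and was -0.06 with the block. Lists called moved from 1 to 2 with the stricter filter and with counts divided by 4, the added list being the S100 family in both. They moved to 3 without number 3 (4 with the block) and to 0 with fry and with an estimated correlation. Without 1 library 2 to 18 were called, with 16 without B2 replicate 3 and 18 without DMSO replicate 3. Removing 1 library of a pair leaves its partner unbalanced. The S100 family was also called without B2 replicate 2 and without DMSO replicate 3. The ribosomal protein list was called without B2 replicate 1, without each DMSO replicate and without number 3, higher with B2 without DMSO replicate 1 and lower in the others. The epithelial and fibroblast list kept its direction, with an adjusted p of 0.996 with an estimated correlation, 0.972 with fry and 5.46e-09 to 0.0941 without 1 library. Of 93 named genes, 20 changed sign under at least 1 alternative and 4 passed the threshold under 1, each without number 3 and with the block. These 4 were S100A14, KRT8, KRT18 and KRT19, all higher with B2. The cause of the other shifts was not tested. A count of 3 corresponded to 0.0386 to 0.0537 CPM, and near that level counting error adds to the spread.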

Other observations

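The test across replicate numbers, the contrast of number 3 with numbers 1 and 2, the genes named here and the tests of shared handling, of each lymphocyte list on its own, of T cell receptor genes, of the epithelial sums within pairs, of macrophage-like differentiation, of a response of epithelial genes to B2 and of overlapping genes were chosen after the values were seen. Replicate number 3 separated the libraries far more than treatment did, which did not hold for numbers 1 and 2. B2 replicates 1 and 2 correlated at 0.976 (Pearson r of log2 CPM across genes), as did the libraries numbered 3. The same-numbered libraries correlated at 0.959 for number 1 and 0.973 for number 2. In the edgeR fit with treatment and number, 461 of 17224 genes differed between numbers at an adjusted p below 0.05, 369 of them highest in number 3, 77 in number 2 and 15 in number 1. Macrophage genes were among those that differed: SIGLEC1, a sialic acid receptor, averaged 499 CPM in the libraries numbered 3 against 3.60 and 2.86 CPM in numbers 1 and 2 (adjusted p = 4.3e-07), and the lipopolysaccharide co-receptor CD14 averaged 115 against 1.03 and 0.488 CPM (adjusted p = 2.3e-06). The complement gene C1QC averaged 42.2 against 0.535 and 0.219 CPM, the scavenger receptor CD163 43.1 against 0.349 and 0.771 CPM, and S100A9 637 against 31.3 and 18.9 CPM (adjusted p = 5.4e-06).

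By list, 21 of 33 interferon-stimulated genes, 18 of 34 monocyte and macrophage markers, 13 of 28 NF-kB targets and 7 of 21 chemokine genes differed between numbers, each highest in number 3. Their median log2 contrasts were 2.23, 1.59, 1.55 and 1.41. The DNA replication list had a median of -0.74, cholesterol synthesis -0.55, G2/M -0.52 and ribosomal proteins -0.51, where the median of all genes was -0.05. Few of their members differed between numbers: 1 of 45 DNA replication, 3 of 25 cholesterol synthesis, 0 of 40 G2/M and 0 of 74 ribosomal protein genes. Camera called 28 of the 44 lists at the preset correlation and 0 with an estimated one (interferon-stimulated genes, adjusted p = 0.0938; monocyte and macrophage markers, adjusted p = 0.0993; G2/M, adjusted p = 0.249), with 2 libraries behind number 3.

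Depth is an unlikely source of the resemblance of same-numbered libraries, since number 3 held both the smallest and the largest total. Thinning to the smallest total, a small step that could remove few calls, left 100% of the 461 genes differing. After each library's trend with transcript length and GC content was removed 96.96% of them still differed, and 882 genes were called. Most of the 461 (369) were highest in number 3, where the GC trend was near 0 (Spearman across genes 0.04 with B2, 0.09 with DMSO). The trend was 0.20 and 0.48 in number 1 and -0.27 and -0.55 in number 2. Correlations of same-numbered deviations were not recomputed after the correction. Length and GC bias is therefore not excluded as a source of the resemblance within numbers 1 and 2. T cells in the libraries numbered 3 are argued against by the 7 genes of the T cell receptor complex, which summed to 0.31 and 0.36 CPM there against 0 to 0.43 CPM elsewhere, with CD2 at 3.38 and 4.57 CPM and 0 counts for CD3D, CD3E, CD3G, TRBC1 and TRBC2. NK cells and a small share of B cells stay open. The pooled T, NK and B cell markers had a median contrast of 0.13 (95% bootstrap interval -0.08 to 0.67, 17 genes). That lies under a bound of 1 set beforehand, which does not serve pooled markers. B cell markers alone had a median of -0.08 (interval -0.37 to 0.67), and 0 of 9 differed between numbers. They showed no rise, although a baseline such as that of FCER2 (289 to 688 CPM) would hide a small share. The 8 T and NK cell markers went both ways (median 0.63, interval -0.57 to 3.28). CD2 and IL7R were highest in number 3, and the other 6, with ZAP70 at 0 and 0.129 CPM there, did not pass the threshold. Macrophage-like differentiation of those cultures is a candidate explanation, with the G2/M list at a median of -0.52 (camera adjusted p = 2.0e-07 at the preset correlation, 0.249 with an estimated one), but macrophage RNA from elsewhere was not excluded. Shared handling cannot be told apart from cultures that truly differed (smallest correlation of same-numbered deviations 0.21), because the labels do not say what a number marks.

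The higher epithelial transcripts in B2 libraries may come from RNA of epithelial cells in part of the libraries. A second list of epithelial genes was drawn up after the keratin values were seen and before its own members were measured. Of its 38 tested genes, 13 (34.2%) had DMSO replicates 1 and 2 as their lowest libraries. In 10000 expression-matched random lists the median was 7.89% and the 95th percentile 15.8%. Members of the random lists were drawn independently, so that percentile is too low for genes that vary together. The pattern itself was taken from the keratins, and any joint change of epithelial genes could give it. The second list therefore does not single out RNA of epithelial cells. MAL2 read 4.38, 4.15 and 4.04 CPM in the B2 libraries and 0, 1.198 and 4.10 CPM in the DMSO libraries, whereas the most abundant member, SPINT1, was highest in DMSO replicate 1 at 79.3 CPM. The summed CPM of that list was 117, 105 and 137 with B2 and 133, 83.1 and 141 with DMSO, lower with B2 in 2 of 3 pairs, a tally that rests on SPINT1: without it the sum averaged 63.2 CPM with B2 and 54.9 CPM with DMSO and was higher with B2 in 2 of 3 pairs (exact sign-flip p = 0.5). A response to B2 stays open, since the summed CPM of the first list was higher with B2 in 3 of 3 pairs (exact sign-flip p = 0.25, the smallest possible) while the groups overlapped (exact permutation p = 0.2, where the smallest possible is 0.1).

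Some genes were at 0 in some libraries and abundant in others, which may reflect reads assigned to 1 of several overlapping genes. Of 14 such genes among those tested (0 counts in at least 1 library and at least 10 CPM in another), 78.6% had exons overlapping another gene on the same strand, against 17.9% of 9431 other genes reaching that level (Fisher's exact p = 1.4e-06). Without the filter on low counts there were 19, of which 78.9% overlapped (Fisher's exact p = 1.3e-08). They include the readthrough genes PPAN-P2RY11, ISY1-RAB43 and BIVM-ERCC5. The 3 tested ones without overlap were ADAMDEC1, CHIT1 and HLA-L, and the first pair of these are macrophage genes highest in the libraries numbered 3. No biological explanation was tested for this pattern.

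The 6 libraries make 10 splits into 3 and 3, too few for a share below 0.05. The real split called 0 genes, where the highest other split called 1, and 1 list, where the highest other called 26. A real count of 0 fixes the outcome of the comparison for genes, which therefore says nothing. Splits calling many lists point to a structure of the samples, here number 3 against the rest. Splits with both libraries numbered 3 on the same side called 21, 26, 24 and 26 lists. Splits that kept numbers 1 and 2 together but parted number 3 called only 5 and 3. Among the splits that part all 3 pairs, the other 3 called 0 genes each and 1, 3 and 5 lists without the block, and with it 1 of them called 2 genes.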
